A study of Mus musculus with 15 samples.

How the data were processed

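The data were RNA-seq read counts of 15 libraries from epidermis and tongue of newborn mice at postnatal day 1, wild type or with the Tmprss11 protease gene cluster targeted by gene editing. Per the labels' protocols, epidermis was separated from dermis after heating in EDTA. Complementary DNA was made with the SMARTer V4 kit for low input, libraries were made with the TruSeq v2 kit, and both ends of each fragment were read on a NextSeq500 sequencer. These kits do not mark strand as far as the labels state, so reads of a gene and of an antisense gene that overlaps it cannot be told apart.

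Reads were aligned with STAR 2.5.2a to GRCm38.p3 (mm10), per the submitters' processing notes, which also name DESeq2, edgeR and limma without versions or roles. The read counter, its strand setting and the annotation release are not given in the sources used here. The authors deposited a table of counts, whole reads per Ensembl gene with no normalization, which is the unit that was tested. They also deposited a table of signal values for the same genes and libraries, in which each count had been divided by a constant of its library and rounded to 2 decimals. Checked on the files, that constant was the library total times a factor of the library, as in CPM of a TMM-scaled library size.

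The tables held 23422 entries, of which 23420 were mouse genes and 2 were transgene sequences named beta-lac and LacZ. The transgene entries were left out of library sizes and tests and are reported as levels. Entries at 0 in all libraries numbered 23, and 68 entries had no symbol. Coordinates were taken from GENCODE release M21 on GRCm38, the build the submitters' notes name. In that release 23337 of the IDs were found and 83 were not.

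Groups and replicate numbers came from the sample titles. The labels give each library an A-number as well. Read as the name of an animal, it gave 9 animals, 6 of which supplied both tissues. In all 6 the balance of Xist against Y-linked reads was alike in the 2 tissues. The A-numbers fall in 3 ranges, written A32x, A34x and A38x here. The labels do not say whether a range marks a litter or a day, so the range was treated as a batch that may hold either. Beyond these numbers the labels give no statement on whether the samples of a group were separate animals, and the p-values measure the spread between these samples.

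Within each comparison, genes were filtered with filterByExpr at a minimum count of 10, scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, two-sided) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. CPM values use the TMM-scaled library size and were computed here within each comparison, so that a group's mean differs slightly between comparisons. The comparisons were knockout against wild type in epidermis, the same in tongue, the difference of these effects between tissues, and wild-type epidermis against wild-type tongue. In the last, a log2 value above 0 means higher in epidermis. Intervals are at 95%.

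Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (edgeR on the same counts, limma 3.58.1). The fry test asks whether the genes of a list move on balance one way and does not compare a list with other genes. There were 39 lists, 21 of them on proteases, the cornified envelope, barrier lipids, keratinocyte layers and stress responses, and 18 on other cell types, sex and RNA quality. A list needed 3 tested members. P-values were adjusted over the lists of a comparison. Members were also counted after adjustment over the list alone.

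The groups, comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names the targeted genes, and up to 10 genes in each direction with the largest changes (6 for the wild-type tissues and for the difference between tissues). These had to pass the threshold, not overlap between groups and reach a mean CPM of 1, and unnamed gene models and pseudogenes were left out. From each list it names up to 3 members past the threshold or, where none passed, the 2 with the highest mean CPM. Where fewer than 10 genes passed, the 10 with the smallest p were taken. Not every gene taken by the rule is printed. Of the 7 targeted genes, 6 were analysed and the other was not analysed here.

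The pipeline was tested on simulated data, drawn from the means and library sizes of the real libraries with 200 genes changed by known folds. Only genes at a mean CPM of 1 or more were changed. Each gene was drawn independently, without the movement that genes of a real library share. The shares recovered below thus hold for such data and do not measure recovery in the real libraries. For epidermis, 61.7% of the genes changed 4-fold and 12% of those changed 2-fold were recovered among 15778 genes. For tongue, 98% and 70% were recovered among 15531 genes. For the difference between tissues the shares were 68% and 14% among 17745 genes, and for the wild-type tissues 91.8% and 30% among 15957 genes. False calls were 8 of 90, 8 of 157, 5 of 88 and 4 of 113 calls in these simulations. A simulated list of 20 genes changed 1.5-fold gave p = 0.00179 in epidermis and p = 7.5e-05 in tongue with an estimated correlation in camera. The real lists had a median estimated correlation of 0.331 in epidermis and 0.252 in tongue. Simulated lists with shared movement of that size were not tested, so these values do not measure how often a real list would pass. Of the unchanged simulated lists, only that of epidermis fell under 0.05, in fry and before adjustment.

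Same-numbered epidermis libraries of the 2 genotypes deviated together from their group means (r = 0.61, 0.20 and 0.43 across genes for the 3 pairs), which by a rule fixed in advance counts as pairing. Animals of a pair differ, and 2 of the 3 pairs share an A-number range. The blocked value is printed beside a result where it changed a call. Library pairs within a group differed by more than sampling noise (chi-square per degree of freedom 7.47 to 194), so no library was counted as a duplicate.

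Alternatives were RLE and upper-quartile factors, no filter and a filter at 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample weights, limma-trend on the deposited signal table at a pseudocount of 1, a fit without robust estimation, all 15 libraries in 1 fit, blocks by replicate number, animal or A-number range, and leaving out each library in turn. A block by sex, fits without mt-Rnr1 and mt-Rnr2, without the A32x libraries, on the A38x libraries alone, and A-number range blocks for the tissue comparisons and the list tests were chosen after the data were seen.

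Shares of a single library carry Wilson intervals at 95%, of which the widest reached 0.0306 percentage points to either side. Intervals of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.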

Results

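Epidermis and tongue of newborn mice were compared between wild-type animals and animals in which the 7 HAT/DESC protease genes (Tmprss11a to Tmprss11g) had been targeted by multiplexed gene editing. Of these genes 6 were analysed. They encode serine proteases with a single transmembrane segment that are made mostly by surface epithelia, and Tmprss11f encodes HAT-like 4. The libraries were 3 of wild-type epidermis, 4 of knockout epidermis, 4 of wild-type tongue and 4 of knockout tongue. By their A-numbers they came from 9 animals, 6 of which gave both tissues. All 4 knockout animals gave both.

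Counted reads ran from 10117938 in epidermis WT 1 to 17819847 in tongue KO 4. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 35.5% to 40.8% of reads in the 8 tongue libraries. They took 29.5 ± 13.2% in wild-type epidermis (n = 3) and 20.8% to 22.8% in the 4 knockout epidermis libraries, and the spread of the wild-type epidermis came from WT 1 at 44.6%. Epidermis WT 1 stood apart from the other epidermis libraries in the genome as a whole, with a mean correlation of levels of 0.888 where the others had 0.944 to 0.960. The first principal component of the epidermis libraries held 58.8% of the variance and set WT 1 at 114 and KO 1 at 42.6, with the others between -46.3 and -15.8. In tongue KO 3 stood apart, at -53.8 on a first component of 32.3% of the variance where the others lay between -16.9 and 18.1, and it is 1 of the 2 knockouts in each A38x tongue value. All 3 wild-type epidermis libraries had more Y-linked than Xist reads, against 2 of 4 in each of the other groups.

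**Figure D1:**
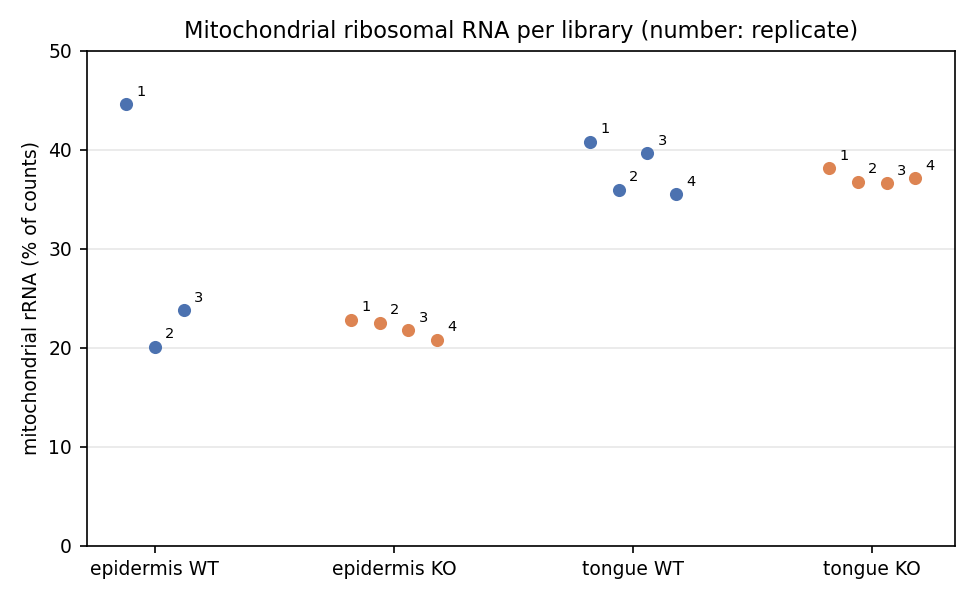
Share of reads in mt-Rnr1 and mt-Rnr2 in each library, in percent. Epidermis WT 1 held 44.6% where the other epidermis libraries held 20.1% to 23.8%.

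The targeted genes were expressed in a tissue-specific way in wild-type animals. In epidermis Tmprss11f made up 92.7 ± 1.25% of the summed CPM of the 6 genes (n = 3), and in tongue Tmprss11a made up 63.5 ± 1.91% (n = 4). None of the 6 analysed genes was absent from the knockouts. Over all genes only Tmprss11a and Tmprss11b in tongue passed, and no targeted gene passed in epidermis. Over the targeted genes alone, Tmprss11a in epidermis and Tmprss11g in both tissues did not pass. Summed over the 6 genes, CPM went from 344 ± 13.5 in wild-type tongue to 131 ± 6.28 in knockout tongue (n = 4 each), and from 292 ± 43.4 (n = 3) to 184 ± 60.1 (n = 4) in epidermis. The genes lie on the minus strand of chromosome 5 within 444 kb, in the order Tmprss11d, Tmprss11a, Tmprss11g, Tmprss11f, Tmprss11b and Tmprss11e. Reads over an edited gene can still be counted when its protein is lost, so these levels do not measure loss of protease.

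**Figure D2:**
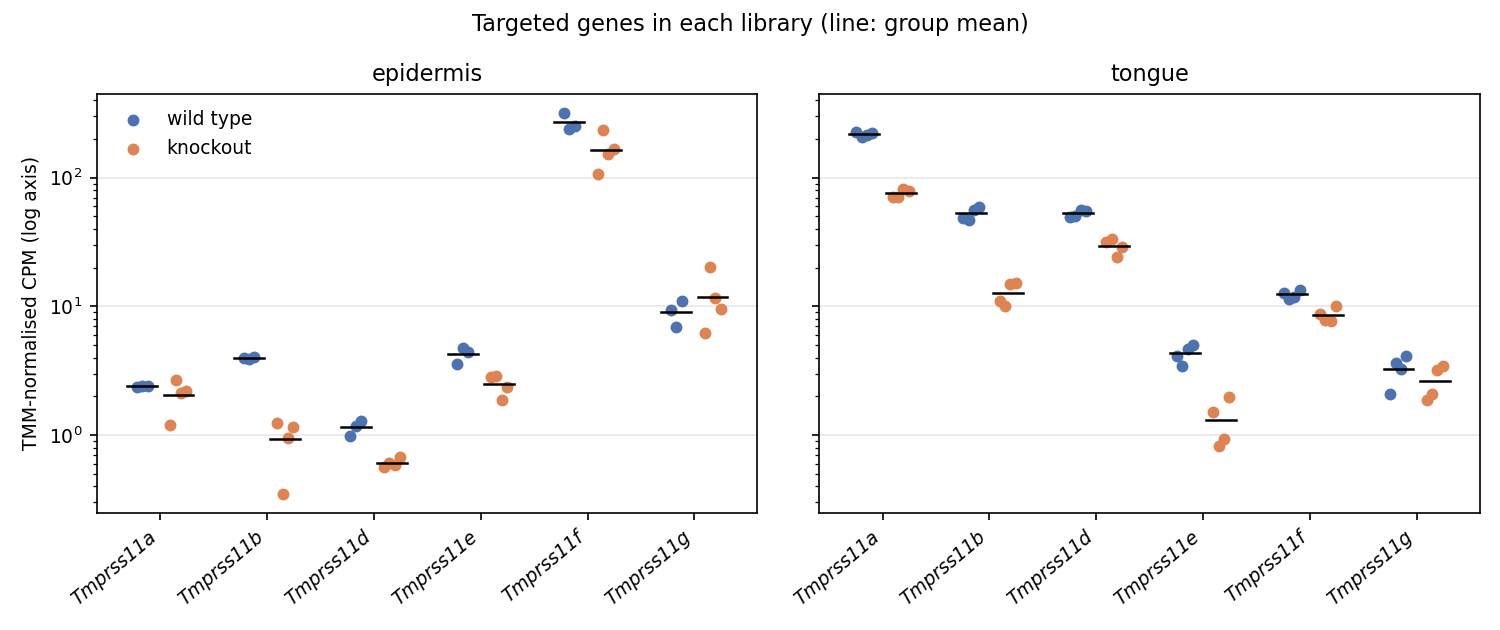
CPM of the 6 targeted genes in each library, by tissue and genotype. Every knockout library lay below every wild-type library for Tmprss11a, Tmprss11b, Tmprss11d, Tmprss11e and Tmprss11f in tongue, and for Tmprss11b, Tmprss11d, Tmprss11e and Tmprss11f in epidermis.

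**Figure D3:**
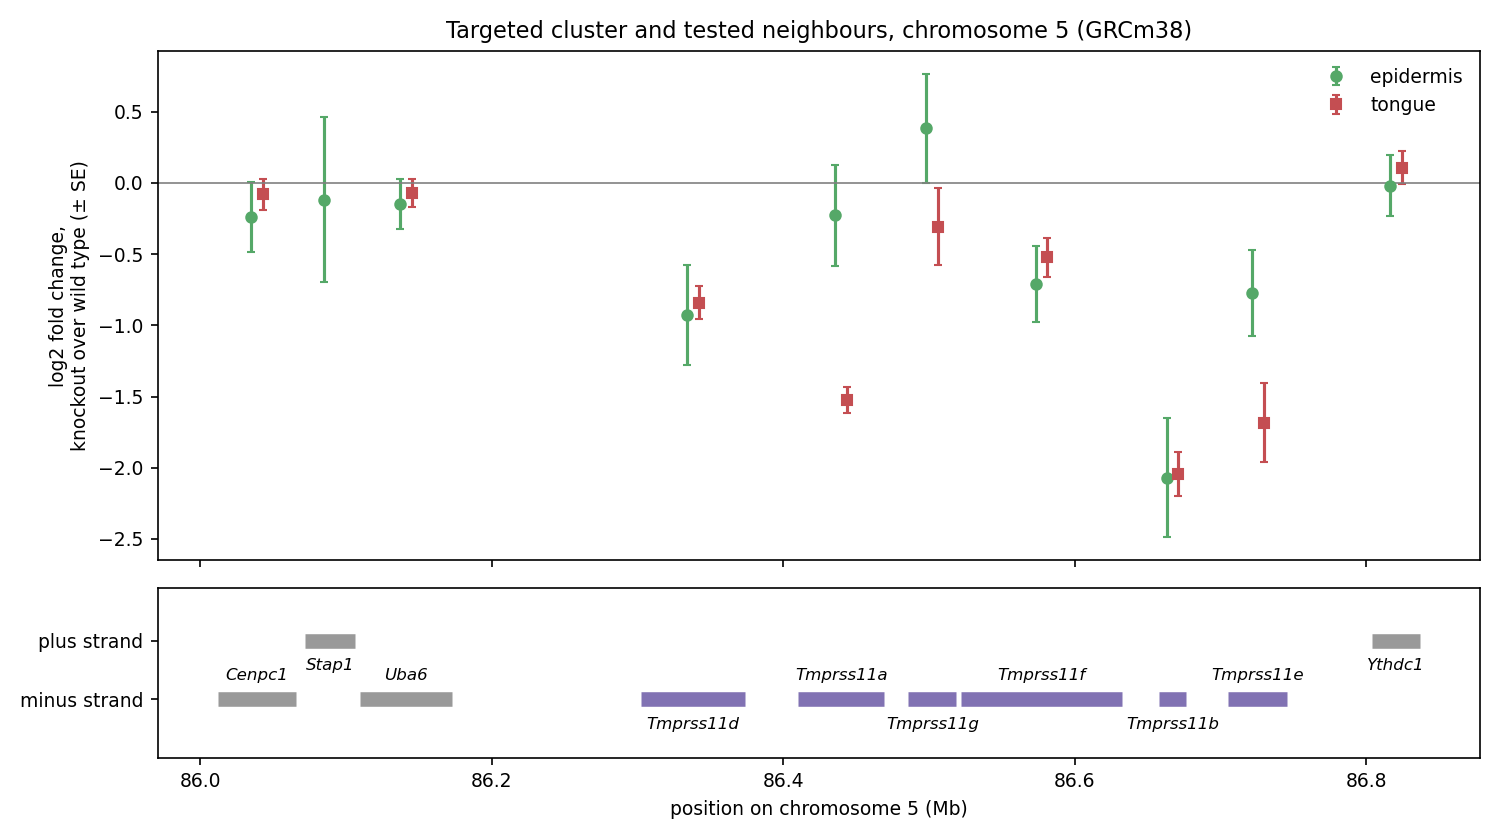
Log2 fold changes of knockout against wild type along the Tmprss11 cluster and its neighbours on chromosome 5. The neighbours Cenpc1, Uba6 and Ythdc1 lay between -0.24 and 0.11 in both tissues.

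In knockout epidermis Tmprss11b fell from 3.97 ± 0.0873 CPM in wild type (n = 3) to 0.927 ± 0.406 (n = 4), 23.4% of the wild-type level (log2 fold change -2.07, SE 0.42; adjusted p = 0.00398 over the targeted genes alone). Tmprss11f, the main HAT/DESC protease of this tissue, fell from 271 ± 43.6 CPM (n = 3) to 166 ± 54.1 (n = 4), 61.2% of wild type (log2 fold change -0.71, SE 0.27). Tmprss11d went from 1.16 ± 0.155 to 0.610 ± 0.0442 CPM (log2 fold change -0.93) and Tmprss11e from 4.26 ± 0.594 CPM to 58.7% of that level (log2 fold change -0.77). The adjusted p of Tmprss11d, Tmprss11e and Tmprss11f over the targeted genes alone was 0.0448. Tmprss11a, at 2.40 ± 0.0403 CPM in wild type, and Tmprss11g, at 9.09 ± 2.08, did not pass (log2 fold changes -0.23 and 0.38, adjusted p = 0.537 and 0.410 over the targeted genes alone).

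The calls of Tmprss11d, Tmprss11e and Tmprss11f in epidermis were fragile. That of Tmprss11b held in each of the 21 other settings in which it was tested, with adjusted p over the targeted genes alone of at most 0.0336. Blocked by replicate number, Tmprss11f had adjusted p = 0.0998 and Tmprss11d and Tmprss11e had 0.119. Without WT 1 the values for Tmprss11f and Tmprss11d were 0.103 and 0.0622, and Tmprss11e kept its call at 0.0482. Without WT 2 they were 0.122 for Tmprss11f and 0.156 for Tmprss11d and Tmprss11e, and without WT 3 they were 0.171, 0.221 and 0.175 for Tmprss11f, Tmprss11d and Tmprss11e. Without KO 1 all 3 genes had 0.0708 and without KO 4 all 3 had 0.0930. Without KO 3 Tmprss11d and Tmprss11f had 0.124 and Tmprss11e had 0.129. Without KO 2 all 3 calls held. Among the A38x epidermis libraries (2 of each genotype) the log2 fold changes were -1.91 for Tmprss11b, -0.62 for Tmprss11f, -1.10 for Tmprss11e and -0.97 for Tmprss11d. Their edgeR adjusted p over the targeted genes alone was 2.6e-04, 0.00121, 0.00376 and 0.0730.

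Over all genes none passed in edgeR with all 7 epidermis libraries and no block, the targeted genes included. With the A-number range as a block Irf7 alone passed, lower in knockout (edgeR adjusted p = 0.0451), and without the A32x libraries Fos alone, higher in knockout (edgeR adjusted p = 0.0425). The genes with the smallest p included the polyamine enzyme Odc1 at 26.3 ± 2.59 CPM in wild type and 14.8 ± 3.21 in knockout (log2 fold change -0.83). The growth factor gene Hgf stood at 4.82 ± 1.19 against 1.67 ± 0.710 CPM (-1.54), and the EGF-family ligand gene Ereg at 79.3 ± 16.8 against 164 ± 48.7 (1.05). The sterol transporter gene Abcg1 stood at 6.70 ± 0.876 against 16.0 ± 5.94 CPM (1.26) and the repressor gene Bcl6 at 15.3 ± 2.82 against 27.6 ± 6.76 (0.85). Tdrd1 (-1.25), Rragd (-0.73) and Trim6 (-1.51) were among them too. Within A38x the log2 fold changes had the same signs, at -0.91 for Odc1, -1.61 for Hgf, 1.28 for Ereg, 1.68 for Abcg1 and 0.93 for Bcl6. The A38x libraries are part of the 7 by which these genes were picked, so like signs lend no independent support.

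No structural gene of the epidermis passed, which with these libraries does not show equal levels. Among the abundant ones, the suprabasal keratin Krt1 stood at 19525 ± 6516 CPM in wild type (n = 3) and 22971 ± 6287 in knockout (n = 4), and Krt10 at 13417 ± 4369 and 15466 ± 3815 CPM. The basal keratin Krt5 stood at 2215 ± 617 and 2311 ± 197 CPM, and the filaggrin-family gene Flg2 at 6778 ± 1318 and 6667 ± 1763. Lce1m of the late cornified envelope, whose relatives are close in sequence, stood at 1141 ± 264 and 1166 ± 415 CPM. Of the genes for barrier lipids, the transporter gene Abca12 stood at 1456 ± 103 and 1589 ± 385 CPM and the elongase gene Elovl4 at 755 ± 292 and 856 ± 208. The protease inhibitor gene Spink5 stood at 1643 ± 632 and 1859 ± 491 CPM and the kallikrein gene Klk7 at 759 ± 206 and 895 ± 229. The adhesion genes Cdh1 (log2 fold change 0.29) and Ctnnb1 (0.15) did not pass either.

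Many of the calls of gene lists in epidermis hung on single libraries. With a preset correlation camera passed 24 of 37 lists, with 11 left without WT 1, the library that stood apart, and 14 without KO 2, and with an estimated correlation 0 (smallest adjusted p = 0.102); fry passed 0. Barrier lipid genes were above 0 in 33 of 36 (median log2 fold change 0.21, camera adjusted p = 3.2e-05), and adjusted p = 0.472 with an estimated correlation. Without WT 1 the camera adjusted p of that list was 0.491, and without KO 2 it was 0.116. Suprabasal keratinocyte genes were above 0 in 15 of 16 (median 0.20, adjusted p = 0.00119), with adjusted p = 0.472 with an estimated correlation, and had a median of 0.01 and adjusted p = 0.820 without WT 1. Mitochondrially encoded genes were below 0 in 7 of 7 (median -0.60, adjusted p = 5.2e-06; mt-Co1 -0.53, mt-Nd1 -0.71), with adjusted p = 0.354 with an estimated correlation. Their median was 0.00 and their adjusted p 0.666 without WT 1, the library richest in mitochondrial ribosomal RNA.

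The camera calls of 3 further lists in epidermis held without WT 1. Immediate early and heat shock genes, taken as 1 list, were above 0 in 16 of 20 (median log2 fold change 0.56, camera adjusted p = 1.9e-09). Klf4 stood at 0.43 and Klf6 at 0.58. The list had adjusted p = 0.354 in camera with an estimated correlation and a median of 0.76 in A38x. Cell cycle genes were below 0 in 23 of 24 (median -0.19, adjusted p = 1.6e-04; Mki67 -0.12, Top2a -0.09), with adjusted p = 0.412 with an estimated correlation and a median of -0.13 in A38x, where Mki67 stood at 0.04. Without KO 2 the camera adjusted p of the cell cycle list was 0.0848. Skeletal muscle genes were above 0 in 12 of 12 (median 1.25, adjusted p = 1.9e-09; Ttn 0.50, Myh8 1.25), with adjusted p = 0.354 with an estimated correlation, and had a median of 0.15 in A38x, where Ttn (-0.53) and Myh8 (-0.30) lay below 0. Mast cell genes (3 of 3 above 0, adjusted p = 4.1e-05; Cpa3 1.55) and adipocyte genes (5 of 5, adjusted p = 4.0e-04; Fabp4 1.10) leaned the same way, each with adjusted p = 0.354 with an estimated correlation. Muscle, fat and mast cells lie below the epidermis, so these lists can follow how cleanly it was lifted.

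The test of knockout against wild-type epidermis passed 0 of 16073 genes in edgeR. An unadjusted p under 0.05 was found for 187, fewer than the 804 that chance gives. With the A-number range as a block it passed 1 (Irf7), with 1563 at an unadjusted p under 0.05. DESeq2 passed 1 (Tmprss11b; 260 at an unadjusted p under 0.05), limma-voom 0 (1606) and limma-trend 0 (151). Of the genes, 59.6% had an interval within 2-fold of no change, and in simulated data 12% of genes changed 2-fold were recovered. The groups did not overlap for 2.13% of genes, where chance gives 5.71%. The A38x libraries alone passed 604 genes.

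In knockout tongue Tmprss11a fell from 218 ± 7.30 CPM to 75.9 ± 5.52 (n = 4 each), 34.8% of wild type (log2 fold change -1.52, SE 0.09; edgeR adjusted p = 2.3e-05). Tmprss11b fell from 52.8 ± 5.74 to 12.8 ± 2.62 CPM, 24.3% of wild type (log2 fold change -2.04, SE 0.15; edgeR adjusted p = 1.2e-04). Over the targeted genes alone Tmprss11d also fell, from 53.1 ± 3.14 to 29.6 ± 4.19 CPM (log2 fold change -0.84; edgeR adjusted p = 2.2e-05, and 0.0583 over all genes). Tmprss11e fell from 4.33 ± 0.677 to 1.31 ± 0.536 CPM (log2 fold change -1.68; edgeR adjusted p = 8.7e-05 over the targeted genes alone, 0.227 over all). Tmprss11f, a minor member here, went from 12.4 ± 0.862 to 8.60 ± 1.12 CPM (log2 fold change -0.52; edgeR adjusted p = 0.00306 over the targeted genes alone, 0.939 over all).

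Tmprss11g stayed at 3.26 ± 0.864 CPM in wild-type and 2.64 ± 0.792 in knockout tongue (log2 fold change -0.31; edgeR adjusted p = 0.277 over the targeted genes alone). Within A38x the log2 fold changes in tongue were -1.45 for Tmprss11a, -1.94 for Tmprss11b, -1.08 for Tmprss11d and -1.66 for Tmprss11e. For Tmprss11f it was -0.50, and its edgeR adjusted p over the targeted genes alone was 0.0531 there. The 5 calls over the targeted genes alone held whichever library was left out.

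Outside the cluster the tongue genes with the smallest p did not pass. The focal adhesion gene Lims2 stood at 1.99 ± 0.431 CPM in wild type and 4.09 ± 0.572 in knockout (log2 fold change 1.03), and Agfg2 at 4.34 ± 0.553 and 8.08 ± 1.60 (0.90). The taurine transporter gene Slc6a6 stood at 70.8 ± 8.94 and 100.4 ± 15.1 CPM (0.50) and the neurotensin gene Nts at 3.85 ± 1.45 and 1.78 ± 0.347 (-1.11). Of the tongue epithelium genes, mostly keratins, 11 of 14 were above 0, among them Krt13 at 0.11 and Krt4 at 0.22. Their median was 0.10 and their highest log2 fold change 0.77 (camera adjusted p = 0.339). Krt6a stood at -0.07. In A38x these 3 stood at -0.17, -0.03 and -0.40. The cornified envelope genes Rptn (2135 ± 350 and 2028 ± 467 CPM) and Sprr3 (621 ± 169 and 639 ± 72.7) did not pass and stood at -0.51 and -0.30 in A38x. Ttn of muscle (log2 fold change 0.24) and Col3a1 of connective tissue (0.07) did not pass either.

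Cell cycle genes were below 0 in 24 of 24 in knockout tongue (median log2 fold change -0.32, camera adjusted p = 3.0e-15), with adjusted p = 0.231 with an estimated correlation. Of its members Mki67 stood at 145 ± 14.5 and 124 ± 35.2 CPM and Top2a at 117 ± 7.84 and 98.2 ± 20.6 (n = 4 each). Within A38x the median was -0.15. Mast cell genes were below 0 in 6 of 7 (median -0.30, camera adjusted p = 2.4e-04; Cpa3 -0.27, Cma1 -0.30), with adjusted p = 0.747 with an estimated correlation and a median of -0.58 in A38x. Other epithelial serine proteases and their inhibitors were above 0 in 8 of 9 (median 0.20, camera adjusted p = 0.0146; Tmprss13 0.15, Spint1 0.34), with adjusted p = 0.889 with an estimated correlation and a median of 0.44 in A38x. The list of targeted genes was below 0 in 6 of 6 and was the only one of 35 to pass with an estimated correlation (adjusted p = 8.5e-04) and in fry (adjusted p = 3.0e-04).

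The test of knockout against wild-type tongue passed 2 of 15741 genes in edgeR. An unadjusted p under 0.05 was found for 496, fewer than the 787 that chance gives. DESeq2 passed 4, limma-voom 3 and limma-trend 2, and all were targeted genes. Of the genes, 88.2% had an interval within 2-fold of no change, and in simulated data 70% of genes changed 2-fold were recovered. The groups did not overlap for 2.37% of genes, where chance gives 2.86%. The A38x libraries alone passed 15 genes.

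Tmprss11a was the targeted gene whose knockout effect parted most between tissues, with a log2 fold change of -1.52 in tongue and -0.23 in epidermis. The difference of 1.30 (SE 0.26) passed over the targeted genes alone (edgeR adjusted p = 8.6e-04) and not over all genes. It passed over the targeted genes alone in each of the 31 other settings run, with adjusted p of at most 0.0181. For Tmprss11b the difference was 0.02, for Tmprss11d -0.08 and for Tmprss11f -0.16, with no difference called for these genes. Tmprss11e (0.95, adjusted p = 0.116 over the targeted genes alone) and Tmprss11g (0.72, adjusted p = 0.336) did not pass. Within A38x the difference for Tmprss11a was 1.27 (edgeR adjusted p = 9.6e-04 over the targeted genes alone). Among other genes with small p, none past the threshold, were Egr1 (1.70), Clmp (1.76), Rhoj (1.26), Ereg (1.11) and Agfg2 (-1.16).

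Of the gene lists, camera passed 12 of 39 for the difference between tissues with a preset correlation, 0 with an estimated one (smallest adjusted p = 0.478), and fry 0. Skeletal muscle genes were above 0 in 13 of 13 (camera adjusted p = 3.6e-07), with adjusted p = 0.759 with an estimated correlation. Mast cell genes were above 0 in 7 of 7 (median 1.22, adjusted p = 9.7e-08), with adjusted p = 0.478 with an estimated correlation. Immediate early and heat shock genes were above 0 in 16 of 20 (median 0.35, camera adjusted p = 1.6e-04), with adjusted p = 0.830 with an estimated correlation. Without epidermis WT 1 their camera adjusted p was 0.152. The test passed 0 of 17935 genes in edgeR, with 299 at an unadjusted p under 0.05, fewer than the 897 that chance gives. DESeq2 passed 1 (Tmprss11a; 316 at an unadjusted p under 0.05), limma-voom 0 (902) and limma-trend 0 (243). Without epidermis KO 1 edgeR passed 1 gene, Tmprss11a. The tissues of 1 animal were treated as independent, and in simulated data 14% of genes changed 2-fold were recovered.

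Wild-type epidermis and wild-type tongue differed in most genes tested, many keratins among them. Suprabasal keratinocyte genes were higher in epidermis in 15 of 15 (median log2 fold change 2.10, camera adjusted p = 2.1e-07), with adjusted p = 0.399 with an estimated correlation. Tongue epithelium genes, mostly keratins, were lower in epidermis in 12 of 14 and higher in 1 (median -6.79, camera adjusted p = 6.6e-08). With an estimated correlation the camera adjusted p was 0.166. The differentiation keratin Krt1 was at 17620 ± 5689 CPM in epidermis (n = 3) and 28.9 ± 9.07 in tongue (n = 4; log2 fold change 9.25), and Flg2 was at 6148 ± 1289 against 1.97 ± 0.796 (11.61). Krt77 of sweat ducts and suprabasal skin (9.76), the envelope protein gene Lce1m (12.26) and the skin caspase gene Casp14 (8.48) were higher in epidermis too. The hard keratins Krt36 (390 ± 59.5 CPM in tongue; -9.02) and Krt84 (376 ± 46.4; -9.11) were higher in tongue, as were Krt24 (-7.16), the secreted inhibitor gene Slpi (249 ± 58.7; -6.63) and Sprr3 (655 ± 182; -6.78). Lce3b was higher in tongue (-6.46), unlike Lce1m, with the caution that relatives in this family are close in sequence.

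Among the targeted genes, Tmprss11a (log2 fold change -6.72), Tmprss11d (-5.70) and Tmprss11b (-3.95) were higher in wild-type tongue, while Tmprss11f (4.23) and Tmprss11g (1.25) were higher in epidermis. Tmprss11a stood at 230 ± 7.24 CPM in tongue and 2.17 ± 0.00915 in epidermis (edgeR adjusted p = 7.7e-08), and Tmprss11f at 13.1 ± 0.924 and 246 ± 43.2 (edgeR adjusted p = 1.3e-07). Tmprss11e did not pass (log2 fold change -0.24; edgeR adjusted p = 0.403). Within A38x the log2 fold changes were -6.75, -5.74 and -4.12 for Tmprss11a, Tmprss11d and Tmprss11b, and 4.02 and 1.02 for Tmprss11f and Tmprss11g. The related protease genes Tmprss13 (2.56) and Prss8 (2.40) were higher in epidermis.

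Barrier lipid genes were higher in epidermis in 33 of 36 (median log2 fold change 2.43, camera adjusted p = 2.2e-17), with adjusted p = 0.154 with an estimated correlation, and included Sdr9c7 (3.42) and Lipm (3.33). Genes of filaggrin processing were higher in 13 and lower in 2 of 16 (adjusted p = 1.7e-08), with adjusted p = 0.154 with an estimated correlation, and included Casp14, Ggct (7.61) and Hal (6.96). Cornified envelope genes were higher in 17 and lower in 3 of 23 (adjusted p = 1.7e-06), with adjusted p = 0.154 with an estimated correlation, and included Ivl (8.02) and Hrnr (4.99). Cholesterol synthesis genes were higher in 16 and lower in 1 of 21 (adjusted p = 9.4e-05), with adjusted p = 0.474 with an estimated correlation.

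Lists of deeper tissue were higher in tongue, which was taken whole. Skeletal muscle genes were higher there in 13 of 13 (median log2 fold change -9.08, camera adjusted p = 4.1e-24), with adjusted p = 0.154 with an estimated correlation. Endothelial genes followed in 9 of 9 (median -6.57, adjusted p = 2.2e-17), with adjusted p = 0.154 with an estimated correlation, and fibroblast genes in 12 of 12 (median -5.34, adjusted p = 1.8e-09), with adjusted p = 0.166 with an estimated correlation. Sln (514 ± 66.8 CPM in tongue; -11.23), Tnnc2 (1499 ± 152; -9.28), Pecam1 (-6.57) and Dpt (-7.69) stood for these groups. Nuclear genes of the respiratory chain were higher in tongue in 21 of 21 (median -1.98, adjusted p = 1.4e-05), with adjusted p = 0.474 with an estimated correlation, among them Cycs (-3.05).

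The test of wild-type epidermis against wild-type tongue passed 10540 of 16577 genes, 5307 higher and 5233 lower in epidermis. Camera passed 22 of 36 lists with a preset correlation, 0 with an estimated one and fry 29. The groups did not overlap for 65.8% of genes, where chance gives 5.71%. The A38x libraries alone passed 11826 genes. Wild-type epidermis was all male by its reads and tongue was not, and Xist (-3.71, edgeR adjusted p = 0.0743) and the Y-linked gene Ddx3y (0.36, edgeR adjusted p = 0.792) did not pass. In A38x, where all wild-type animals were male, both passed with the other sign (1.17, edgeR adjusted p = 0.00638, and -0.56, edgeR adjusted p = 0.00117).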

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

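The splits of the A38x libraries, the count of targeted genes in the splits of the difference between tissues, and the tests on the few reads of Tmprss11a, the rate of Y-linked reads, the depth of epidermis WT 1 and the shared A32x batch were chosen after the result was seen. The predictions on reads crossing from tongue, on tissue of a male animal and on another tissue in epidermis WT 1 were written before their tests were run. All of them use the same libraries as the results they test.

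A single library stood far from the rest of its group in 7 of 122 groups of values, and chance gives about 1 in 20, or 6.1. In tongue WT 4 mt-Rnr1 took 1.84% of reads where the other wild-type tongues had 2.08% to 2.12%. In tongue KO 3 mt-Rnr1 took 7.36% (others 1.91% to 2.18%) and mt-Rnr2 29.3% (others 34.8% to 36.0%), so this library held more of the former and less of the latter. It also differed most from the other knockout tongues in levels (chi-square per degree of freedom 57.1 to 60.3, where their other pairs had 15.9 to 23.2). Egr1 stood at 166 CPM in epidermis KO 4 (others 51.7 to 59.8) and Spink5 at 1127 CPM in epidermis KO 1 (others 2054 to 2191). 4933408B17Rik stood at 0.277 CPM in tongue WT 3 (others 0.447 to 0.451) and Lims2 at 2.63 CPM in tongue WT 2 (others 1.73 to 1.80). The tested difference between tissues for Tmprss11a, 1.30, was taken up here because its knockout effect differed between groups.

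Whether chance could give such results was asked by splitting the libraries anew. For the targeted genes in epidermis, 1 of 35 splits, the real one, passed 4 genes over the list alone, and no other split, those parting as many same-numbered pairs included, passed more than 1. In tongue 1 of 35 splits, the real one, passed 5 and the others at most 0. A share of 1 of 35 lies under 0.05, the limit fixed in advance, which argues against chance for these counts. It is the smallest share that 35 splits can give, so chance is not fully excluded. The counts were taken without a block. With the replicate block 1 gene, Tmprss11b, passed in epidermis. Splits with a block were not run, so chance was not tested for the blocked count and is not excluded there. Without a block 3 other splits also passed 1. For wild-type epidermis against wild-type tongue, 1 of 35 splits reached 10540 genes and the others reached at most 0. That share argues against chance there too.

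For the difference between tissues, 10 of 100 splits, the real one included, passed at least the real 1 targeted gene over the list alone, with at most 3 in another split. These splits keep part of a real effect in either tissue and count any targeted gene, so they decide nothing on Tmprss11a. Where no gene passed over all genes, every split does as well (35 of 35 in epidermis with at most 0 in another, 100 of 100 for the difference between tissues with at most 3), and this says nothing on chance. In tongue 3 of 35 splits, the real one included, passed at least the real 2 genes, so chance is not excluded for the bare count. The real 2 genes are both targeted, while the other splits that reached the count passed 0 targeted genes over the list alone. The count thus does not bear on which genes passed. The highest other split, with WT 2, WT 3, WT 4 and KO 2 against the rest, passed 60. That split points to a structure of the tongue samples that crosses genotype. Among the A38x epidermis libraries 1 of 3 splits, the real one, passed 604 genes and the others at most 0, which are too few splits for a share under 0.05.

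Tmprss11a fell in tongue and did not pass in epidermis, and its few epidermal reads could have crossed from tongue libraries. The 20 genes least present in epidermis among those at 200 CPM or more in tongue had a median epidermis to tongue ratio of 0.131%, while Tmprss11a stood at 0.945%, so crossing alone is excluded as their source. Of the 431 genes at that level 67 lay below Tmprss11a. Too few reads to see a fall is excluded for a fall as large as in tongue, since the lower end of the epidermis interval was -1.03 and the tongue log2 fold change -1.52. A smaller fall is within the interval.

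Libraries with more Xist than Y-linked reads still held Y-linked reads, at a rate of 1.02 to 38.8 on the CPM scale, where the 9 male libraries held 323 to 395. A single common rate of crossing between libraries is excluded, because the highest rate was 38.2 times the lowest. Tongue KO 1 had a Y share of 10.7% of the male level. At that share, tongue tissue of a wild-type male would have raised its Tmprss11a to 92.4 CPM. The library held 71.4 CPM, where the other knockout tongues held 77.4 ± 5.70 (n = 3), which argues against wild-type male tongue as the source. Epidermis of a wild-type male, with Tmprss11a at 2.40 CPM, would not have raised it and was not tested. Tissue of a knockout male was not tested either.

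Epidermis WT 1 stood apart and had the smallest depth, but total depth is excluded as the sole source. With the epidermis libraries thinned to 10117819 reads its mean correlation with the 6 others was 0.895, where the others had at least 0.945. The thinned totals included mt-Rnr1 and mt-Rnr2, at 44.6% in WT 1 and 20.1% to 23.8% in the others. Depth in the remaining genes was thus not made equal, and its part was not tested. A lower share of another tissue in WT 1 cannot be told from these data. The lists taken were of fibroblast, muscle, endothelial, leukocyte, melanocyte and adipocyte genes. Among these 6 the highest median of WT 1 against the 6 other libraries was 0.41 (adipocyte genes, 5 genes, SD 1.17). The other medians lay below 0, as a lower share would give. They were -0.997 for fibroblast (10 of 11 genes below 0), -1.05 for muscle (10 of 12) and -1.06 for melanocyte genes (8 of 8). Leukocyte genes lay at -0.621 (9 of 9) and endothelial genes at -0.115 (3 of 6). Suprabasal keratinocyte genes lay at -0.837 (14 of 16), so low medians were not confined to these lists. A batch of the A32x libraries could account in part for WT 1 standing apart, since the deviations of WT 1 and KO 1 had r = 0.608. In WT 1 the nuclear respiratory genes lay at a median of -0.98 (21 of 21 below 0) and the mitochondrially encoded genes at 1.25 (7 of 7 above 0).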

How the results depend on the processing

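The fits without the A32x libraries, on A38x alone, with a sex block, without the mitochondrial ribosomal RNAs and with A-number range blocks for the tissue comparisons and lists were chosen after the data were seen. Unless a cause is given, the cause of a move was not tested.

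In epidermis the count of 0 genes became 1 with DESeq2 and 1 with all 15 libraries in 1 fit (Tmprss11b in both), 1 with A-number range as a block (Irf7, lower), 1 without the A32x libraries (Fos) and 604 in A38x alone (374 up, 230 down). It stayed at 0 with the replicate block and with any library left out (0 to 0). In tongue the count of 2 became 4 with DESeq2 and 15 in A38x alone (6 up, 9 down), with 2 in the replicate block and 2 to 2 over libraries left out. For the difference between tissues the 0 became 1 with DESeq2 and 19 in A38x alone, with 0 in the replicate block and 0 to 1 over libraries left out (1 without epidermis KO 1). For the wild-type tissues the 10540 became 6574 under the filter of 10 CPM in 3 libraries, where fewer genes were tested (9569), 9037 with the replicate block, and 9199 to 12170 over libraries left out.

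Of the list tests, the 24 in epidermis became 0 with an estimated correlation, 0 with fry, 0 with the A-number range block and an estimated correlation, 12 without A32x, 25 with the replicate block, and 11 (without WT 1) to 25 (without KO 4) over libraries left out. The 4 in tongue became 1, 1 and 1 in the first 3 of these, 10 without A32x, 8 with the replicate block and 4 to 12 over libraries left out. The 12 for the difference between tissues became 0, 0 and 0, then 11 with the replicate block and 5 to 15 over libraries left out. The 22 for the wild-type tissues became 0 with an estimated correlation, 0 with the range block and an estimated correlation, 29 with fry, 23 with the replicate block and 19 to 23 over libraries left out. That estimated correlations end most calls follows from their construction, which widens the test by the shared movement of list members.

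Signs changed for estimates that had not passed with all libraries of a comparison. Sign changes of named genes that passed in neither setting were counted against all pairs of named gene and setting. They made up 146 of 1939 pairs in epidermis, 87 of 1941 in tongue, 242 of 2806 for the difference between tissues and 2 of 2613 for the wild-type tissues. The totals include genes that passed, so these are not rates among genes that did not pass. Changes of targeted genes are given apart. Of the targeted genes in epidermis, Tmprss11g was -0.0192 with the range block and Tmprss11a 0.0276 with the sex block. The difference between tissues for Tmprss11b, 0.02, was -0.0204 with upper-quartile factors, -0.00988 without a filter, -0.0230 with the 10 CPM filter, -0.0539 with limma-voom and an animal block, -0.0759 with the replicate block, -0.16 without A32x and -0.14 to 0.24 over libraries left out. It lay below 0 without epidermis KO 1, epidermis KO 4, tongue WT 3, tongue WT 4, tongue KO 1 or tongue KO 2. That for Tmprss11d was 0.41 with limma-trend, 0.00791 with the sex block, 0.10 in A38x and -0.17 to 0.0113 over libraries left out (above 0 without epidermis WT 3). That for Tmprss11f was 0.14 without A32x and -0.40 to 0.00363 over libraries left out (above 0 without epidermis KO 1). Between wild-type tissues Xist was 1.25 with the animal block and 1.17 in A38x, and Ddx3y -0.55 and -0.56, all past the threshold there. These settings compare tissues of the same male animals. Their Xist values thus rest on the few Xist reads of male libraries, whose source was not tested.

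Same-numbered tongue libraries of the genotypes deviated with r = 0.54, 0.14, -0.12 and 0.21, so tongue was not treated as paired.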

Other observations

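The comparisons within A38x, the lists on glucocorticoid, clock and fatty acid genes and their tests were all chosen after the data were seen. Each A38x comparison rests on 2 libraries of each genotype, in which KO 3 alone had more Xist than Y-linked reads, and the knockout animals are the same in both tissues.

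In A38x epidermis several genes known to respond to glucocorticoids were higher in knockout. They included Tsc22d3 (11.2 CPM in wild type and 126 in knockout; log2 fold change 3.49), Zbtb16 (18.2 and 138; 2.93), Fkbp5 (79.9 and 250; 1.65), Klf9 (7.17 and 27.4; 1.93) and the clock gene Per1 (67.2 and 178; 1.40). Serpina3n (4.49), Trp53inp1 (72.8 and 506; 2.80), Txnip (362 and 1376; 1.93) and Fos (40.2 and 185; 2.20) rose as well. Angptl4 (-3.76), Cyp1b1 (-2.64) and the interferon regulator gene Irf7 (-1.98) fell. In A38x tongue Klf15 (2.86 and 23.1; 3.01), Tsc22d3 (65.2 and 178; 1.45), Klf9 (36.5 and 83.9) and Trp53inp1 (64.1 and 140; 1.13) rose. Angptl4 (35.5 and 3.06 CPM, -3.56), the uncoupling protein gene Ucp3 (19.4 and 2.91 CPM, -2.80) and the fatty acid oxidation gene Cpt1a (-1.77) fell. With all tongue libraries these changes were smaller. Klf15 stood at 2.04, Tsc22d3 at 0.79, Klf9 at 0.65 and Trp53inp1 at 0.51. Angptl4 stood at -0.81, Ucp3 at -0.55 and Cpt1a at -0.51 there. The A38x values came from 604 calls in epidermis and 15 in tongue. With all libraries 85 and 3 of these calls had an unadjusted edgeR p under 0.05. Angptl4 is itself a known glucocorticoid response gene and went the other way.

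Lists were less clear than single genes. In A38x epidermis cholesterol synthesis genes were above 0 in 3 of 21 (median -0.49, camera adjusted p = 2.4e-07) and hair follicle genes in 0 of 16 (median -0.93, camera adjusted p = 8.0e-07), each with adjusted p = 0.827 with an estimated correlation. In all epidermis libraries the hair follicle list went the other way (13 of 16 above 0, median 0.95) and the cholesterol list had a median of -0.06.

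Stress hormone signalling in the knockout pups was weighed with a list of glucocorticoid response genes whose values had not been seen. In A38x 8 of its genes passed over all genes in epidermis and 4 in tongue. They are thus among the A38x calls, so the A38x values of this list are not independent of those calls. The values over all libraries include the A38x libraries, so they are not independent of those calls either. In all epidermis libraries 18 of 19 were above 0, with a median of 0.59. Camera with an estimated correlation gave p = 0.0459 (adjusted p = 0.0917 over the 2 tissues), and fry gave p = 0.121. That met the outcome set for such signalling before the test, by the unadjusted camera p alone. The adjusted camera p and the fry p did not pass, so such signalling is not shown. With 1 library left out or with a sex block, the epidermis camera p ran from 0.0469 to 0.237 and 1 of 8 settings lay under 0.05. The lowest was without KO 1 and the highest without WT 1, the library that stood apart. Without WT 1 14 of 19 were above 0 (median 0.45). In tongue 18 of 20 were above 0 (median 0.48; camera p = 0.104 with an estimated correlation; fry p = 0.189), and the hypothesis can be neither kept nor excluded there. The tongue p ran from 0.0203 without KO 2 to 0.290 without KO 4, with medians from 0.32 to 0.65. With A-number range as a block the medians were 0.75 in epidermis (16 of 19 above 0) and 0.42 in tongue, with camera p = 0.0101 and 0.132 with an estimated correlation. In A38x they were 0.85 (14 of 19 above 0) and 0.88, with camera p = 0.0968 and 0.0472 with an estimated correlation. The fry p-values there were 0.0504 and 0.0282.

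A shifted clock phase, as from another time of day at collection, was tested as the median of clock output genes minus that of clock genes of opposite phase, of which the epidermis value of Clock had been seen before. It was -0.31 in epidermis, with 1 of 7 output genes above 0 in all libraries and 4 of 7 in A38x and with the A-number range as a block. In tongue it was 0.29, with every output gene above 0. The named test, fry with signs over both lists, gave p-values of 0.561 in epidermis and 0.400 in tongue, and of 0.821 and 0.00856 in A38x. A difference at or below 0 had been set before the test as the outcome against a shift that raises output genes. Epidermis met that outcome and tongue did not. The rule takes no account of spread, and the Clock value had been seen, so a shift is not excluded in epidermis. In all libraries a shifted phase is thus shown in neither tissue and fully excluded in neither. The lean of the A38x tongue libraries came from the output genes alone, since 3 of 4 genes of opposite phase were above 0 there (median 0.07).

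Less fatty acid signalling, as could lower Angptl4, was tested in A38x with a list of its target genes whose values had not been seen. The median was -0.33 in epidermis (12 of 16 below 0 and 7 past over the list alone, camera p = 0.282 with an estimated correlation) and -0.52 in tongue (17 of 18 below 0, camera p = 0.0586), where 11 of 18 passed over the list alone. The fry p-values were 0.0802 and 0.00450. In all libraries the medians were 0.00 and -0.10. The camera and fry tests part in tongue, so neither tissue settles it, and feeding state, litter and knockout cannot be parted with these samples.

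The transgene sequence beta-lac stood at 12.2 ± 1.07 CPM in wild-type epidermis (n = 3), 11.4 ± 2.93 in knockout epidermis, 42.2 ± 6.54 in wild-type tongue and 30.3 ± 10.2 in knockout tongue (n = 4 each), on the scale of the authors' table. LacZ had group means of 0.573, 0.968, 3.38 and 2.95 CPM in the same order. They were not tested, and the labels do not say that the mice carried them.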
